A study of Homo sapiens with 8 samples.

How the data were processed

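RNA was sequenced from 8 libraries of SUDHL-4 cells, an established line of diffuse large B-cell lymphoma of the germinal-centre type. Per the labels, the cells were control cells of wild-type genotype or cells overexpressing FDX1 (FDX1-OE), and they received DMSO or 5 nM elesclomol (ES) for 48 h, with 2 libraries in each of the 4 groups. The submitters' notes name TRIzol for extraction, a NanoDrop spectrophotometer and a Bioanalyzer for quality control, and the VAHTS Universal V6 kit for the libraries. Per the submitters' processing notes, HISAT2, HTSeq and R 3.2.0 were used with the genome build hg19, and their roles are not given in the sources used here. The gene annotation, the filters and the program that made the values are not given either.

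The deposited values are FPKM, which are reads divided by gene length and library total, made by the authors, for 15597 protein-coding genes in every library. The file headers state no unit, so the unit was read from the values. The values of a gene were whole multiples of a step that scaled with the inverse of its length and of the library total, and these steps gave whole reads for 100% of the genes within a tolerance of 0.02 read. The library totals were fixed from the reads of 204 genes and lay between 33435438 and 35883528 reads. The genes listed held 99.94% of each total, and no gene was at 0 in every library. Recovered reads were used for depth, for the floor of 3 reads and for 1 alternative test. On 8 simulated libraries the same recovery returned all 8 totals exactly, every read count of 99.3% of 15049 genes and 99.95% of the reads. At these depths 3 reads of a gene of 1 kilobase came to between 0.0836 and 0.0897 FPKM. Floors and intervals cover counting error only.

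Differences between groups were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a fit of the 4 group means to all 8 libraries (4 residual degrees of freedom), empirical Bayes moderation with a mean trend (6.6 prior degrees of freedom) and Benjamini-Hochberg adjustment over the genes tested in each comparison. Genes with at least 1 FPKM in at least 2 libraries were tested, which left 9805 genes, and a gene was called at an adjusted p below 0.05. Fold changes are on the scale of FPKM + 1, which understates the change of genes with low values and can enlarge or turn the interaction where the groups start from different low values. The 5 comparisons were ES against DMSO in control cells, ES against DMSO in FDX1-OE cells, FDX1-OE against control cells in DMSO, FDX1-OE against control cells in ES, and the interaction, which is the ES response of FDX1-OE cells minus that of control cells. All of these tests were two-sided. The fold changes of comparisons that share no library were correlated across genes, which are not independent replicates.

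The groups, comparisons, gene lists, rule for named genes and most alternatives were chosen before the data were examined. That plan named a test for read counts, with limma on log2 values where the data proved to be normalized. The filter at 1 FPKM, the use of log2(FPKM + 1) in place of log2 CPM in the list tests, and the use of FPKM in place of CPM in the limits of 5 were chosen after the data were seen. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these libraries alone. An exact two-sided permutation test of 2 libraries against 2 cannot go below p = 0.33 and was not used.

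For gene lists, camera from limma was run with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 24 lists with at least 5 tested members. It asks whether the genes of a list changed more than the other genes. The same test with the correlation estimated for each list, and fry, which tests whether the genes of a list move one way on balance, were run as alternatives. Members that rose or fell were counted at an adjusted p below 0.05 over all tested genes and, separately, adjusted over the list alone. The 29 lists held genes of the lipoylation pathway, copper handling, metallothioneins with other MTF1 targets, the heat shock response, NRF2 targets, the ATF4 stress response, the unfolded protein response of the endoplasmic reticulum (ER), iron-sulfur cluster assembly, nuclear-encoded oxidative phosphorylation (OXPHOS), mitochondrially encoded genes, the TCA cycle, glycolysis and hypoxia, cholesterol synthesis, p53 targets, S phase, mitosis, replication-dependent histones, interferon-stimulated genes, germinal-centre B cells, plasma cells, NF-kB targets, MHC class II, pro-apoptotic BCL2 family members, iron handling, ribosome biogenesis, immediate early genes, and markers of T and NK cells, of myeloid cells and of epithelial and stromal cells. A further 5 lists, of interferon ligands, chemokines, nucleic acid sensors, MHC class I presentation and cancer-testis genes, were written after the values were seen. Their members were counted apart from the others, and list tests of them are not given because the genes were chosen from rises already seen. Genes were matched by symbol, and by older symbols through GENCODE v29 and RefSeq tables of a GRCh38 assembly, which were used for names and transcript lengths only.

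The genes named in each comparison are FDX1, then, by size, the 6 largest rises and the 6 largest falls among called genes with a mean of at least 5 FPKM over the libraries compared. Outside the interaction, the libraries of the groups compared also had to lie apart, and loci without a gene name were left out. For up to 6 called lists, the 3 members with the smallest p were named too. FDX1, SLC31A1, ATP7A, MT1X, MT2A, SLC30A1, HSPA1A, HMOX1, DDIT3, LIAS and DLAT could be named whether called or not, and HSPA1A and HMOX1 were below the filter. Any other gene named was chosen after its values were seen.

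The alternatives were scaling by medians of ratios (RLE), no filter on low values, a mean of at least 5 FPKM, pseudocounts of 0.1 and 5 in place of 1, voom on the recovered reads, a replicate block, a fit to the 4 libraries compared, a change of at least 2 times as a further threshold, Spearman in place of Pearson correlation, and leaving out each library in turn. Each changed 1 choice except voom, which changed the values, the weights and the filter (at least 10 reads in at least 2 libraries) together. The interaction was also taken from ratios of mean FPKM with nothing added, without a test. Where a library is left out, the lone library of its group is assumed to vary like the other groups. Counts of list members under these alternatives, and the limits that say when a value has moved, were added after the data were seen.

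The tests were also run on simulated data with known changes. Of genes changed by 1.5 times, 34.0% to 89.4% were found, with the lowest share in the interaction. Of genes changed by 2 times, between 92% and 100% were found, and 3.3% to 11.8% of the calls were false. Most genes were left unchanged, so the false share need not hold for ES. A raised list was called in all 5 comparisons, and 0 of 24 unchanged lists were called in each. The simulated genes varied independently, so list counts cannot show how often lists of correlated genes are falsely called. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.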

Results

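RNA from 8 libraries of SUDHL-4 cells was sequenced to ask, as the series title has it, how overexpression of FDX1 changes gene expression under elesclomol. FDX1 encodes ferredoxin 1, a mitochondrial iron-sulfur protein that passes electrons to other enzymes and acts in protein lipoylation. Elesclomol (ES) carries copper into cells. Control cells and cells overexpressing FDX1 (FDX1-OE) each received DMSO or 5 nM ES for 48 h, and each of the 4 groups had 2 libraries. The library totals in DMSO were 34735595 and 35883528 reads for control cells and 35221521 and 33435438 reads for FDX1-OE cells. In ES they were 33511325 and 33932213 reads for control cells and 34779685 and 35270214 reads for FDX1-OE cells. A principal component analysis placed 78% of the variance of log2(FPKM + 1) on the axis that parted the ES libraries from the DMSO libraries. On that axis the control libraries in ES lay at 10.41 and 6.15, the FDX1-OE libraries in ES at 26.8 and 26.86, and the 4 DMSO libraries between -19.87 and -14.47.

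FDX1 was higher in each FDX1-OE library than in each control library. Its level was 23.89 FPKM ± 2.40 (SD, n = 2) in control cells in DMSO and 71.14 FPKM ± 1.79 (SD, n = 2) in FDX1-OE cells in DMSO. In ES it was 21.34 FPKM ± 0.0251 (SD, n = 2) in control cells and 83.67 FPKM ± 1.65 (SD, n = 2) in FDX1-OE cells. FDX1 was thus 2.90 times higher in FDX1-OE cells in DMSO (log2 change 1.54, SE 0.07, adjusted p = 1.88e-06) and 3.79 times higher in ES (log2 change 1.92, adjusted p = 1.83e-07). Reads of the transgene and of the endogenous gene were not told apart, and the labels do not say what vector, if any, the control cells carry.

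**Figure D1:**
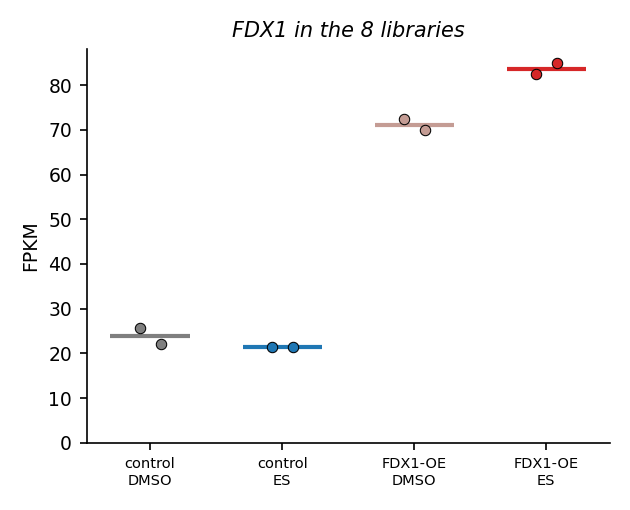
FDX1 level in FPKM (vertical axis) in each of the 8 libraries by group (horizontal axis), where points are libraries and bars are means of 2 libraries. The group means are 23.89 and 21.34 FPKM in control cells in DMSO and ES, and 71.14 and 83.67 FPKM in FDX1-OE cells.

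Elesclomol in control cells shows the effect of the drug without added FDX1. IFI6, whose product limits cell death and viral replication, rose 10.0 times, from 6.22 FPKM ± 0.716 to 71.9 FPKM ± 14.6 (SD, n = 2 each; log2 change 3.33, SE 0.17, adjusted p = 1.6e-06). IFIT3, an antiviral RNA-response protein, rose 6.55 times, from 10.99 to 78.5 FPKM (SE 0.15 on the log2 scale, adjusted p = 1.8e-06). Among the falls FKBP4, a co-chaperone of HSP90, was at 0.601 times its DMSO level (log2 change -0.73, adjusted p = 4.69e-06).

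Of 9805 genes tested, 3767 passed in control cells, 2498 higher and 1269 lower with ES. A change of at least 2 times was reached by 93 of the higher genes and by 1 of the lower genes, RASA4, which was named after its value was seen. Most changes were small, and the split between higher and lower depended on scaling: with RLE scaling 1682 genes were higher and 2123 lower, and 2951 of the main calls were shared. RLE scaling moved the median log2 change of all genes from 0.06 to -0.02 here and from 0.09 to -0.03 in FDX1-OE cells, a shift of over 0.1 in the latter.

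Besides IFI6 and IFIT3, the rises named by size were IFITM1 (8.49 times), IFIT2 (6.98 times), SAMD9L (6.36 times) and IFI35 (6.15 times). All are induced by interferon. The falls named by size were DDN (0.507 times), KREMEN2 (0.544 times), SAPCD2 and HSPE1 (each 0.556 times), RABAC1 (0.585 times) and INKA1 (0.589 times). HSPE1 encodes the small subunit of the mitochondrial chaperonin. The metallothionein MT2A, which binds copper and zinc, rose 3.69 times, from 91.9 to 344.2 FPKM (log2 change 1.88, SE 0.11, adjusted p = 2.01e-06), and MT1X rose 1.52 times (adjusted p = 0.00207). DDIT3, a transcription factor of the stress response, rose 1.3 times (adjusted p = 0.00919). It did not pass without control DMSO replicate 1 (adjusted p = 0.0637) or without the filter on low values (adjusted p = 0.0598). DLAT, a lipoylated subunit of pyruvate dehydrogenase, was at 0.863 times its DMSO level (adjusted p = 0.0194). This call was lost without control DMSO replicate 1 (adjusted p = 0.128) and without control ES replicate 1 (adjusted p = 0.102). FDX1 itself did not pass (log2 change -0.15, adjusted p = 0.0913), but it was lower with RLE scaling (adjusted p = 0.0162) and without control DMSO replicate 2 (adjusted p = 0.0194). The copper importer SLC31A1 (log2 change -0.03, adjusted p = 0.852), the exporter ATP7A (0.21, adjusted p = 0.104; 0.0492 with voom), the zinc exporter SLC30A1 (0.08, adjusted p = 0.503) and the lipoate synthase LIAS (-0.11, adjusted p = 0.395) did not pass.

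In control cells camera called 7 of 24 lists, 4 of them up and 3 down with ES, and 0 of the 7 held with an estimated correlation, where 4 lists had an unadjusted p below 0.05. Of 30 interferon-stimulated genes 28 rose and 0 fell, or 29 and 0 adjusted over the list alone (median log2 change 1.86, adjusted p = 6.02e-21; adjusted p = 0.348 with an estimated correlation). IFI44L (4.30 times), SAMD9L and XAF1 (6.63 times), a pro-apoptotic interferon-induced gene, had the smallest p of the list. XAF1 went from 0.517 to 9.07 FPKM, so its fold rests in part on the added 1. The myeloid markers CD68 and FCER1G rose beside them, by 1.56 and 1.298 on the log2 scale. Of 21 NF-kB targets 16 rose and 0 fell, the same counts adjusted over the list alone (median 0.55, adjusted p = 8.91e-07; adjusted p = 0.274 with an estimated correlation), among them the cytokine subunit EBI3 (5.71 times), LTB (2.15 times) and CD83 (1.66 times). S phase genes followed, with 21 of 34 risen and 1 fallen, or 22 and 1 adjusted over the list alone (median 0.23, adjusted p = 9.54e-05; adjusted p = 0.274 with an estimated correlation). CCNE2, a cyclin of the start of S phase, rose 2.15 times, TYMS 1.54 times and RRM2 1.49 times. Of 27 germinal-centre B-cell genes 11 rose and 1 fell, also adjusted over the list alone (median 0.09, adjusted p = 0.0404; adjusted p = 0.348 with an estimated correlation). That last call was lost with RLE scaling, where 7 members rose (adjusted p = 0.129), in a fit to the 4 libraries (adjusted p = 0.0571), and without control DMSO replicate 1 (adjusted p = 0.106) or control ES replicate 2 (adjusted p = 0.0721). The count of risen members was 7 without control DMSO replicate 1 or 2 and 6 without control ES replicate 1.

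Ribosome biogenesis genes fell in control cells, 21 of 31 against 1 that rose, or 25 and 1 adjusted over the list alone (median -0.24, adjusted p = 6.18e-12; adjusted p = 0.166 with an estimated correlation). RRS1 (0.642 times), NOP16 (0.648 times) and BOP1 (0.735 times) act in the assembly of the large ribosomal subunit. Of 18 heat shock genes 13 fell and 2 rose, or 15 and 2 adjusted over the list alone (median -0.30, adjusted p = 1.41e-07; adjusted p = 0.274 with an estimated correlation). Besides FKBP4, the chaperone HSPA8 was at 0.711 times and the HSP90 activator AHSA1 at 0.754 times its DMSO level. Nuclear OXPHOS genes changed less, with 22 of 76 fallen and 4 risen, or 22 and 3 adjusted over the list alone (median -0.07, adjusted p = 6.46e-05; adjusted p = 0.542 with an estimated correlation and 0.131 with fry). ATP5F1D (0.648 times) and ATP5MC3 (0.731 times) encode parts of ATP synthase, and NDUFB8 (0.765 times) a part of complex I. The count of OXPHOS genes that fell was 36 with RLE scaling, 12 without the filter, 12 without control DMSO replicate 1 and 13 without control ES replicate 2.

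The other 17 lists were not called in control cells, though NRF2 targets were called down without control DMSO replicate 2 (adjusted p = 0.0411). With fry, ATF4 stress genes (adjusted p = 0.00572), p53 targets (0.00487) and histones (0.0129) were called up. Pro-apoptotic genes (0.0223) and iron handling (0.00572) were too. In the lipoylation pathway 2 of 12 genes rose and 3 fell, and in copper handling 3 of 14 rose and 3 fell. The ATF4 stress response had 13 of 27 genes risen and 6 fallen, NRF2 targets 5 of 21 and 7, the ER unfolded protein response 4 of 21 and 3, iron-sulfur cluster assembly 2 of 20 and 5, and the TCA cycle 4 of 16 and 1. Risen and fallen genes numbered 7 and 7 of 28 in glycolysis and hypoxia, 3 and 6 of 23 in cholesterol synthesis, 8 and 1 of 21 among p53 targets, 4 and 7 of 32 in mitosis, and 3 and 0 of 11 histones. They numbered 5 and 3 of 11 plasma cell genes, 2 and 3 of 13 MHC class II genes, 6 and 2 of 12 pro-apoptotic genes, 7 and 4 of 21 iron handling genes and 4 and 2 of 16 immediate early genes. Adjusted over the list alone, the counts that differed were 2 and 1 for the TCA cycle, 8 and 7 for glycolysis and hypoxia, 6 and 3 for plasma cell genes, 11 and 4 for iron handling and 5 and 2 for immediate early genes. For the TCA cycle camera pointed down while the median and mean were 0.02. The means of copper handling and of glycolysis and hypoxia, and the median of mitosis, were also above 0 where the test pointed down.

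**Figure D2:**
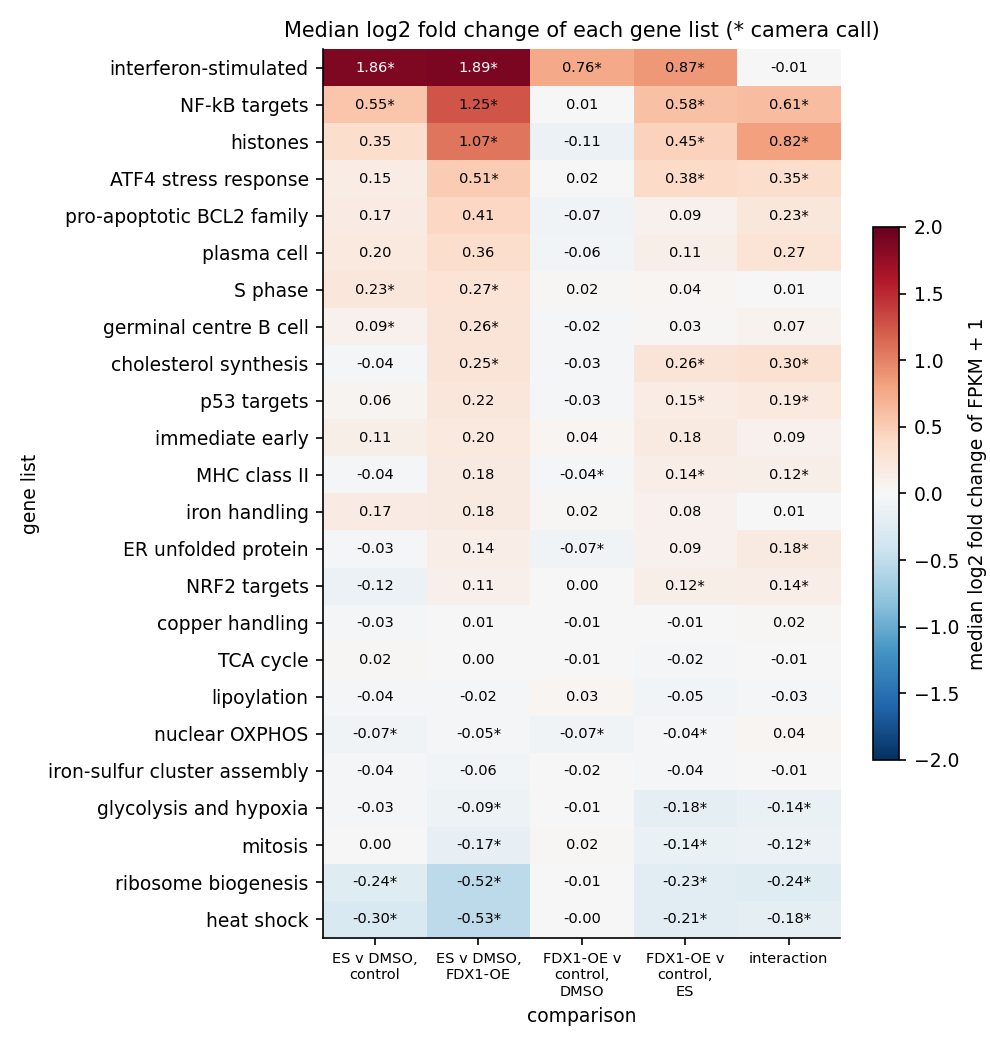
Median log2 fold change of FPKM + 1 (color scale and printed values) for each of 24 gene lists (vertical axis) in the 5 comparisons (horizontal axis), with an asterisk where camera called the list. Interferon-stimulated genes have medians of 1.86 and 1.89 for ES in control and FDX1-OE cells and -0.01 in the interaction.

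FDX1-OE cells show the effect of ES where FDX1 is raised. EBI3, a subunit of interleukins 27 and 35 and an NF-kB target, rose from 2.07 to 41.1 FPKM. On FPKM + 1 this was 13.7 times (log2 change 3.78, SE 0.16, n = 2 per group, adjusted p = 1.43e-07). The chemokine CXCL10 rose 10.3 times, from 5.95 FPKM ± 0.132 to 70.9 FPKM ± 3.50 (SD, n = 2 each; log2 change 3.37, SE 0.11, adjusted p = 3.46e-08). ATF5, a transcription factor of the mitochondrial and integrated stress responses, rose 5.57 times (log2 change 2.48, adjusted p = 4.58e-09). NOP16, which acts in ribosome assembly, was at 0.498 times its DMSO level.

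With ES 5510 genes passed in FDX1-OE cells, 3632 higher and 1878 lower. A change of at least 2 times was seen for 285 higher and 8 lower genes; DDN, TRIB1, SLC17A9, SAPCD2, FKBP4 and NOP16 were among these 8, with TRIP10 and SLX1B, which were named after their values were seen. Scaling turned the split here as well, with 2351 genes higher and 3105 lower under RLE and 4229 main calls shared. After EBI3 and CXCL10 the rises named by size were IFITM1 (10.2 times), DHRS2 (8.33 times), RTP4 (8.28 times) and TNFSF10 (8.04 times). TNFSF10 encodes the death ligand TRAIL. Besides NOP16 the falls named by size were DDN (0.378 times), TRIB1 (0.474 times), SLC17A9 (0.476 times), SAPCD2 (0.491 times) and FKBP4 (0.492 times). MT2A rose 3.85 times, from 130.5 to 503.3 FPKM (adjusted p = 4.39e-07), MT1X 2.01 times, SLC30A1 1.3 times (adjusted p = 0.00445) and DDIT3 1.85 times. DLAT fell to 0.703 times its DMSO level (log2 change -0.51, SE 0.06, adjusted p = 5.98e-05). FDX1 rose 1.17 times (adjusted p = 0.0124). That call was lost with RLE scaling (adjusted p = 0.279) and without FDX1-OE DMSO replicate 2 (adjusted p = 0.0752) or FDX1-OE ES replicate 2 (adjusted p = 0.0638). SLC31A1 (log2 change 0.04, adjusted p = 0.74), ATP7A (0.18, adjusted p = 0.118) and LIAS (adjusted p = 0.904) did not pass.

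Of the 24 lists 12 were called in FDX1-OE cells, 7 up and 5 down with ES, and 0 held with an estimated correlation (4 at an unadjusted p below 0.05). Interferon-stimulated genes rose in 29 of 30 cases with 0 falling, also adjusted over the list alone (median 1.89, adjusted p = 1.97e-14; adjusted p = 0.256 with an estimated correlation). XAF1 (6.62 times), ISG20 (3.60 times), an exonuclease that degrades RNA, and IFI44L (3.53 times) had the smallest p. XAF1 went from 1.79 to 17.2 FPKM, a higher start than in control cells, so its like folds in the genotypes rest on the added 1. CD68 and FCER1G rose by 2.66 and 1.70 on the log2 scale. Of 21 NF-kB targets 19 rose and 0 fell, also adjusted over the list alone (median 1.254, adjusted p = 3.64e-09; adjusted p = 0.251 with an estimated correlation). CCL22 rose 7.73 times and LTB 3.68 times. ATF4 stress genes rose in 19 of 27 cases and fell in 1, or 20 and 1 adjusted over the list alone (median 0.51, adjusted p = 0.000506; adjusted p = 0.251 with an estimated correlation). Beside ATF5, CHAC1, which degrades glutathione, rose 3.19 times and PPP1R15A 2.95 times. Of 34 S phase genes 21 rose and 2 fell, or 22 and 2 adjusted over the list alone (median 0.27, adjusted p = 0.00903; adjusted p = 0.251 with an estimated correlation). Histones rose in 8 of 11 cases with 0 falling, also adjusted over the list alone (median 1.07, adjusted p = 0.0163; adjusted p = 0.251 with an estimated correlation), a call lost with voom (adjusted p = 0.282) and without the filter (adjusted p = 0.321). Germinal-centre B-cell genes rose in 16 of 27 cases and fell in 3 (median 0.26, adjusted p = 0.018; adjusted p = 0.251 with an estimated correlation). Cholesterol synthesis genes rose in 14 of 23 cases and fell in 1 (median 0.25, adjusted p = 0.0215; adjusted p = 0.251 with an estimated correlation). The counts of both were the same adjusted over the list alone.

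Ribosome biogenesis genes fell in 30 of 31 cases in FDX1-OE cells and rose in 0, also adjusted over the list alone (median -0.52, adjusted p = 1.26e-16; adjusted p = 0.0863 with an estimated correlation). RRS1 (0.544 times) and the nucleolar MYBBP1A (0.627 times) joined NOP16. Of 18 heat shock genes 13 fell and 3 rose, also adjusted over the list alone (median -0.53, adjusted p = 3.58e-06; adjusted p = 0.251 with an estimated correlation). HSP90AB1 was at 0.591 times and the co-chaperone STIP1 at 0.603 times. Mitosis genes fell in 15 of 32 cases and rose in 3, also adjusted over the list alone (adjusted p = 4.77e-05; adjusted p = 0.251 with an estimated correlation). PLK1, a mitotic kinase, was at 0.598 times, CCNB1 at 0.652 times and CDC20 at 0.739 times its DMSO level. Nuclear OXPHOS genes went both ways, 21 of 76 falling and 13 rising, also adjusted over the list alone (adjusted p = 0.00903; adjusted p = 0.472 with an estimated correlation), a call lost with fry (adjusted p = 0.255) and at a mean of at least 5 FPKM (adjusted p = 0.0914). Glycolysis and hypoxia genes fell in 11 of 28 cases and rose in 8, or 12 and 8 adjusted over the list alone (median -0.09, adjusted p = 0.0215; adjusted p = 0.251 with an estimated correlation), a call lost with RLE scaling (adjusted p = 0.082) and at a mean of at least 5 FPKM (adjusted p = 0.0542). With RLE scaling 26 mitosis genes and 40 OXPHOS genes fell and 14 S phase genes rose, and 13 OXPHOS genes fell without FDX1-OE DMSO replicate 1, FDX1-OE DMSO replicate 2 or FDX1-OE ES replicate 1.

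The remaining 12 lists were not called in FDX1-OE cells, though the pro-apoptotic BCL2 family was called up with RLE scaling (adjusted p = 0.0419) and without FDX1-OE DMSO replicate 1 (adjusted p = 0.0325). With fry all of these lists were called except iron-sulfur cluster assembly (adjusted p = 0.219) and the TCA cycle (0.139). The lipoylation pathway was called down (0.0363) and the others up, among them NRF2 targets (0.00378) and p53 targets (0.000168). Risen and fallen genes numbered 1 and 3 in the lipoylation pathway, 4 and 3 in copper handling, 9 and 8 among NRF2 targets, 10 and 1 in the ER unfolded protein response and 3 and 6 in iron-sulfur cluster assembly. They numbered 4 and 4 in the TCA cycle, 10 and 2 among p53 targets, 8 and 3 among plasma cell genes, 8 and 1 in MHC class II, 7 and 1 among pro-apoptotic genes, 9 and 4 in iron handling and 8 and 1 among immediate early genes. Adjusted over the list alone the counts were the same except for iron-sulfur cluster assembly, with 3 and 5. For NRF2 targets camera pointed down while the median was 0.11 and the mean 0.16. It also pointed down for copper handling, with a median of 0.01 and a mean of 0.05, and for the TCA cycle, with a median above 0.

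FDX1-OE against control cells in DMSO compares the genotypes without the drug. An effect of FDX1 was not told apart from one of how the cells were made. RSAD2, which encodes the antiviral enzyme viperin, was at 15.7 FPKM ± 6.21 in FDX1-OE cells against 3.27 FPKM ± 0.403 (SD, n = 2 each). On the scale of FPKM + 1 this was 3.79 times higher (log2 change 1.92, SE 0.20, adjusted p = 0.00145). IFIT1, which binds foreign RNA, was 3.42 times higher (log2 change 1.77, SE 0.14, adjusted p = 0.000227). XBP1, a transcription factor of the unfolded protein response and of plasma cells, was at 0.704 times (adjusted p = 0.015; 0.177 without control DMSO replicate 1).

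Of the genes tested 50 passed in DMSO, 42 higher and 8 lower in FDX1-OE cells, and 18 of the higher genes differed by at least 2 times. The count at an unadjusted p under 0.05 was 711. The other largest rises were those of IFITM1 (3.42 times), IFI6 (3.24 times), IFIT3 (3.2 times) and IFIT2 (3.11 times). The largest falls were those of the phosphatase PTPN6 (0.680 times, adjusted p = 0.0163), XBP1, the integrin ITGB2 (0.718 times, adjusted p = 0.017), LAPTM5 (0.747 times, adjusted p = 0.00299), PLEKHA2 (0.767 times) and HMCES (0.776 times). NRROS and VPREB3, named after their values were seen, were the remaining 2 lower genes. Without the filter on low values 2 genes passed, and the 12 named calls other than FDX1 had adjusted p between 0.147 and 0.273. The count was 15 without control DMSO replicate 1, 21 without control DMSO replicate 2 and 32 without FDX1-OE DMSO replicate 2. IFITM1 (adjusted p = 0.0569) and the 6 lower genes (0.0566 to 0.273) were lost without control DMSO replicate 1. PTPN6, ITGB2, PLEKHA2 and HMCES were lost without control DMSO replicate 2 (0.116 to 0.184) or FDX1-OE DMSO replicate 2 (0.0809 to 0.331), and XBP1, ITGB2 and PLEKHA2 without FDX1-OE DMSO replicate 1 (0.0606 to 0.112). MT2A was 1.41 times higher but did not pass (log2 change 0.49, adjusted p = 0.08), though it did with voom (adjusted p = 0.0458), a mean of at least 5 FPKM (0.0489), a fit to the 4 libraries (0.0149) and without FDX1-OE DMSO replicate 1 (0.0194). SLC31A1 (adjusted p = 0.929), ATP7A (0.976), MT1X (0.985), SLC30A1 (0.955), DDIT3 (0.969), LIAS (0.896) and DLAT (0.99) did not pass in DMSO, and their log2 changes lay between -0.13 and 0.06.

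In DMSO camera called 4 lists, 1 up and 3 down in FDX1-OE cells, and 0 held with an estimated correlation (2 at an unadjusted p below 0.05). Of 30 interferon-stimulated genes 19 were higher and 0 lower, or 26 and 0 adjusted over the list alone (median 0.76, adjusted p = 1.98e-54; adjusted p = 0.229 with an estimated correlation and 0.099 with fry). Beside them the myeloid markers CD68 (log2 change 0.41, adjusted p = 0.0659) and FCER1G (0.81, adjusted p = 0.0603) had an unadjusted p below 0.05. The count of interferon-stimulated genes was 0 without the filter, 11 with a pseudocount of 5, 8 without control DMSO replicate 1 and 6 without control DMSO replicate 2. Nuclear OXPHOS genes were shifted down with 0 of 76 passing in limma against 8 lower and 0 higher at an unadjusted p below 0.05, also 0 adjusted over the list alone (median -0.07, adjusted p = 7.03e-09; adjusted p = 0.628 with an estimated correlation). NDUFAB1 (log2 change -0.15, adjusted p = 0.414), NDUFC1 (-0.20, adjusted p = 0.432) and NDUFA1 (-0.23, adjusted p = 0.485) had its smallest p. The call was lost without control DMSO replicate 1 (adjusted p = 0.0704) and with fry (adjusted p = 0.531). In the ER unfolded protein response XBP1 alone passed, also adjusted over the list alone (adjusted p = 8.36e-05; adjusted p = 0.204 with an estimated correlation and 0.099 with fry), and it did not without control DMSO replicate 1 (adjusted p = 0.177), FDX1-OE DMSO replicate 1 (adjusted p = 0.0819) or the filter (adjusted p = 0.273). HSP90B1 (log2 change -0.14, adjusted p = 0.537) and MANF (-0.13, adjusted p = 0.582) came next. MHC class II genes had 0 of 13 passing, with 1 lower at an unadjusted p below 0.05, also 0 adjusted over the list alone (median -0.04, adjusted p = 0.0474; adjusted p = 0.625 with an estimated correlation). HLA-DRB1 (log2 change -0.14, adjusted p = 0.62), HLA-DQB1 (adjusted p = 0.744) and HLA-DQA1 (-0.11, adjusted p = 0.77) had its smallest p. This call was lost with RLE scaling (adjusted p = 0.0568), a mean of at least 5 FPKM (0.0589), a pseudocount of 0.1 (0.0518), a fit to the 4 libraries (0.0809), fry (0.452), and without control DMSO replicate 1 (0.107), control DMSO replicate 2 (0.0924), FDX1-OE DMSO replicate 1 (0.0679) or FDX1-OE DMSO replicate 2 (0.33).

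In the other 20 lists 0 genes passed in DMSO, apart from XBP1, which is also a plasma cell gene. Adjusted over the list alone, 2 germinal-centre B-cell genes were higher and 2 lower, 2 plasma cell genes were higher and 1 lower, and 1 gene was lower in each of glycolysis and hypoxia, cholesterol synthesis, histones and the pro-apoptotic BCL2 family. The count was 0 in the lipoylation pathway, copper handling, heat shock, NRF2 targets, the ATF4 stress response, iron-sulfur cluster assembly, the TCA cycle, p53 targets, S phase, mitosis, NF-kB targets, iron handling, ribosome biogenesis and immediate early genes. In that order 1, 0, 1, 1, 2, 2, 0, 2, 2, 0, 5, 1, 0 and 3 of their genes had an unadjusted p below 0.05 in limma. The test pointed down while the median and mean of NRF2 targets and the mean of ribosome biogenesis genes were above 0.

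FDX1-OE against control cells in ES is the comparison named in the series title. CXCL10, a chemokine that draws T cells, was 5.79 times higher in FDX1-OE cells, at 70.9 FPKM ± 3.50 against 11.5 FPKM ± 2.53 (SD, n = 2 each; log2 change 2.53, SE 0.11, adjusted p = 1.03e-06). ATF5 was 1.93 times higher (161.7 against 83.5 FPKM, SE 0.06 on the log2 scale). INSIG1, a sterol-regulated protein of the ER, was 1.59 times higher (62.3 against 38.8 FPKM, SE 0.05 on the log2 scale). TCL1A, a B-cell oncogene, was at 0.596 times the control level (27.5 against 46.8 FPKM, log2 change -0.75, SE 0.06, adjusted p = 4.21e-05).

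In ES 2094 genes passed, 1331 higher and 763 lower in FDX1-OE cells, and 76 of the higher genes differed by at least 2 times. With RLE scaling 961 were higher and 1273 lower, and 1724 main calls were shared. The count was 748 without control ES replicate 2, 867 without FDX1-OE ES replicate 1 and 1302 without FDX1-OE ES replicate 2. Other rises named by size were CXCL11 (5.18 times), TNFSF10 (4.12 times), IFITM1 (4.10 times), the interferon IFNL3 (4.05 times) and CCL5 (3.94 times). Beside TCL1A the lower genes named were EGR1 (0.582 times, adjusted p = 0.019), SLC17A9 (0.673 times), ITGB2 (0.679 times), RAB3A (0.680 times) and GFI1B (0.684 times). EGR1 was lost without control ES replicate 2 (adjusted p = 0.155), FDX1-OE ES replicate 1 (0.0903), FDX1-OE ES replicate 2 (0.0624) or the filter (0.117), and RAB3A without control ES replicate 2 (0.062) or the filter (0.0558). MT2A was 1.47 times higher (adjusted p = 0.00539; 0.0548 without the filter), MT1X 1.29 times (adjusted p = 0.0411) and DDIT3 1.48 times (adjusted p = 0.00249). MT1X was lost with RLE scaling (adjusted p = 0.0628), with voom (0.0502) and without control ES replicate 1 (0.0776), control ES replicate 2 (0.184), FDX1-OE ES replicate 2 (0.255) or the filter (0.155). DLAT was at 0.823 times the control level (adjusted p = 0.00979; 0.0751 without control ES replicate 2 and 0.0553 without FDX1-OE ES replicate 2). SLC30A1 (log2 change 0.22, adjusted p = 0.107), SLC31A1 (-0.04, adjusted p = 0.82), ATP7A (0.03, adjusted p = 0.878) and LIAS (-0.04, adjusted p = 0.793) did not pass.

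Camera called 13 lists in ES, 8 up and 5 down in FDX1-OE cells, and 0 held with an estimated correlation (7 at an unadjusted p below 0.05). Of 30 interferon-stimulated genes 26 were higher and 0 lower, or 29 and 0 adjusted over the list alone (median 0.87, adjusted p = 2.35e-16; adjusted p = 0.246 with an estimated correlation). MX2 was 3.78 times, DDX58, which encodes the RNA sensor RIG-I, 2.55 times and ISG20 2.00 times higher, and the myeloid markers CD68 and FCER1G were 2.84 and 2.31 times higher. NF-kB targets were higher in 17 of 21 cases and lower in 0, or 18 and 0 adjusted over the list alone (median 0.58, adjusted p = 2.15e-12; adjusted p = 0.0852 with an estimated correlation). CCL22 was 2.78 times, CCL3 2.73 times and TRAF1 2.51 times higher. Of 27 ATF4 stress genes 18 were higher and 0 lower, or 19 and 0 adjusted over the list alone (median 0.38, adjusted p = 1.81e-08; adjusted p = 0.0852 with an estimated correlation). Among them were CHAC1 at 2.06 times and the pseudokinase TRIB3 at 1.66 times. Cholesterol synthesis genes were higher in 14 of 23 cases and lower in 0, or 16 and 0 adjusted over the list alone (median 0.26, adjusted p = 1.81e-07; adjusted p = 0.0852 with an estimated correlation). Examples were the synthase HMGCS1 at 1.51 times and the reductase TM7SF2 at 1.43 times. Histones were higher in 5 of 11 cases and lower in 0, or 6 and 0 adjusted over the list alone (median 0.45, adjusted p = 0.00337; adjusted p = 0.111 with an estimated correlation), a call lost with voom (adjusted p = 0.311) and without the filter (adjusted p = 0.33). Of 21 p53 targets 8 were higher and 2 lower, or 10 and 2 adjusted over the list alone (median 0.15, adjusted p = 0.0167; adjusted p = 0.151 with an estimated correlation), a call lost at a mean of at least 5 FPKM (adjusted p = 0.143). Of 21 NRF2 targets 8 were higher and 1 lower, or 9 and 1 adjusted over the list alone (median 0.12, adjusted p = 0.0233; adjusted p = 0.323 with an estimated correlation). MHC class II genes were higher in 3 of 13 cases and lower in 0, or 6 and 0 adjusted over the list alone (median 0.14, adjusted p = 0.0337; adjusted p = 0.246 with an estimated correlation), a call lost with RLE scaling (adjusted p = 0.0865), with voom (0.064), in a fit to the 4 libraries (0.0663) and without control ES replicate 1 (0.108) or FDX1-OE ES replicate 2 (0.118). Without the filter 5 NRF2 targets and 2 histones were higher, at a mean of at least 5 FPKM 5 NRF2 targets and 4 p53 targets, and with the replicate block 5 MHC class II genes. Without control ES replicate 2 the higher genes numbered 6 in cholesterol synthesis, 5 among p53 targets, 4 among NRF2 targets, 2 among histones and 1 in MHC class II. The numbers were 9, 4 and 5 for cholesterol synthesis, p53 targets and NRF2 targets without FDX1-OE ES replicate 1, and without FDX1-OE ES replicate 2 they were 5 for p53 targets, 5 for NRF2 targets, 2 for histones and 1 for MHC class II.

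Ribosome biogenesis genes were lower in FDX1-OE cells in ES in 19 of 31 cases and higher in 0, or 24 and 0 adjusted over the list alone (median -0.23, adjusted p = 1.88e-13; adjusted p = 0.0852 with an estimated correlation). NCL, which encodes nucleolin, was at 0.775 times, and NOB1 and NOLC1 were each at 0.788 times the control level. Of 32 mitosis genes 8 were lower and 0 higher, also adjusted over the list alone (median -0.14, adjusted p = 2.04e-06; adjusted p = 0.179 with an estimated correlation). PLK1 was at 0.777 times, the spindle factor TPX2 at 0.783 times and UBE2C at 0.821 times the control level. UBE2C was lost without control ES replicate 2 (adjusted p = 0.0524) or FDX1-OE ES replicate 1 (adjusted p = 0.0505). Glycolysis and hypoxia genes were lower in 11 of 28 cases and higher in 2, or 13 and 4 adjusted over the list alone (median -0.18, adjusted p = 0.00193; adjusted p = 0.0852 with an estimated correlation). Of 18 heat shock genes 8 were lower and 3 higher, or 10 and 4 adjusted over the list alone (median -0.21, adjusted p = 0.00247; adjusted p = 0.323 with an estimated correlation). OXPHOS genes were lower in 5 of 76 cases and higher in 0, or 2 and 0 adjusted over the list alone (median -0.04, adjusted p = 0.0278; adjusted p = 0.518 with an estimated correlation), a call lost at a mean of at least 5 FPKM (adjusted p = 0.147), with fry (0.432) and without control ES replicate 1 (0.0996) or FDX1-OE ES replicate 1 (0.167). Lower genes numbered 17 in mitosis and 13 in OXPHOS with RLE scaling, and 2 in OXPHOS without the filter. Without control ES replicate 2 they numbered 10 in ribosome biogenesis, 2 in mitosis, 4 in glycolysis, 5 in heat shock and 0 in OXPHOS. They numbered 2 in mitosis, 5 in heat shock and 1 in OXPHOS without FDX1-OE ES replicate 1, and 5 in mitosis without FDX1-OE ES replicate 2.

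The other 11 lists were not called in ES. The TCA cycle was called down without the filter (adjusted p = 0.0414), iron-sulfur cluster assembly down without FDX1-OE ES replicate 2 (0.0308), and immediate early genes up at a mean of at least 5 FPKM (0.0487) and without control ES replicate 2 (0.0305). With fry all of these lists were called except the lipoylation pathway (adjusted p = 0.0934), iron-sulfur cluster assembly (0.249) and S phase (0.105). The TCA cycle was called down by fry (0.0204) and the others up. Higher and lower genes numbered 0 and 2 in the lipoylation pathway, 1 and 0 in copper handling, 6 and 1 in the ER unfolded protein response, 1 and 2 in iron-sulfur cluster assembly, 0 and 4 in the TCA cycle and 4 and 0 in S phase. They numbered 6 and 2 among germinal-centre B-cell genes, 5 and 3 among plasma cell genes, 4 and 0 among pro-apoptotic genes, 4 and 2 in iron handling and 7 and 2 among immediate early genes. Adjusted over the list alone the counts that differed were 7 and 1 for the ER unfolded protein response, 0 and 5 for the TCA cycle, 1 and 0 for S phase and 8 and 3 for germinal-centre B-cell genes. They were 5 and 4 for plasma cell genes, 5 and 2 for iron handling and 7 and 3 for immediate early genes. For copper handling camera pointed down while the mean was 0.02.

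**Figure D3:**
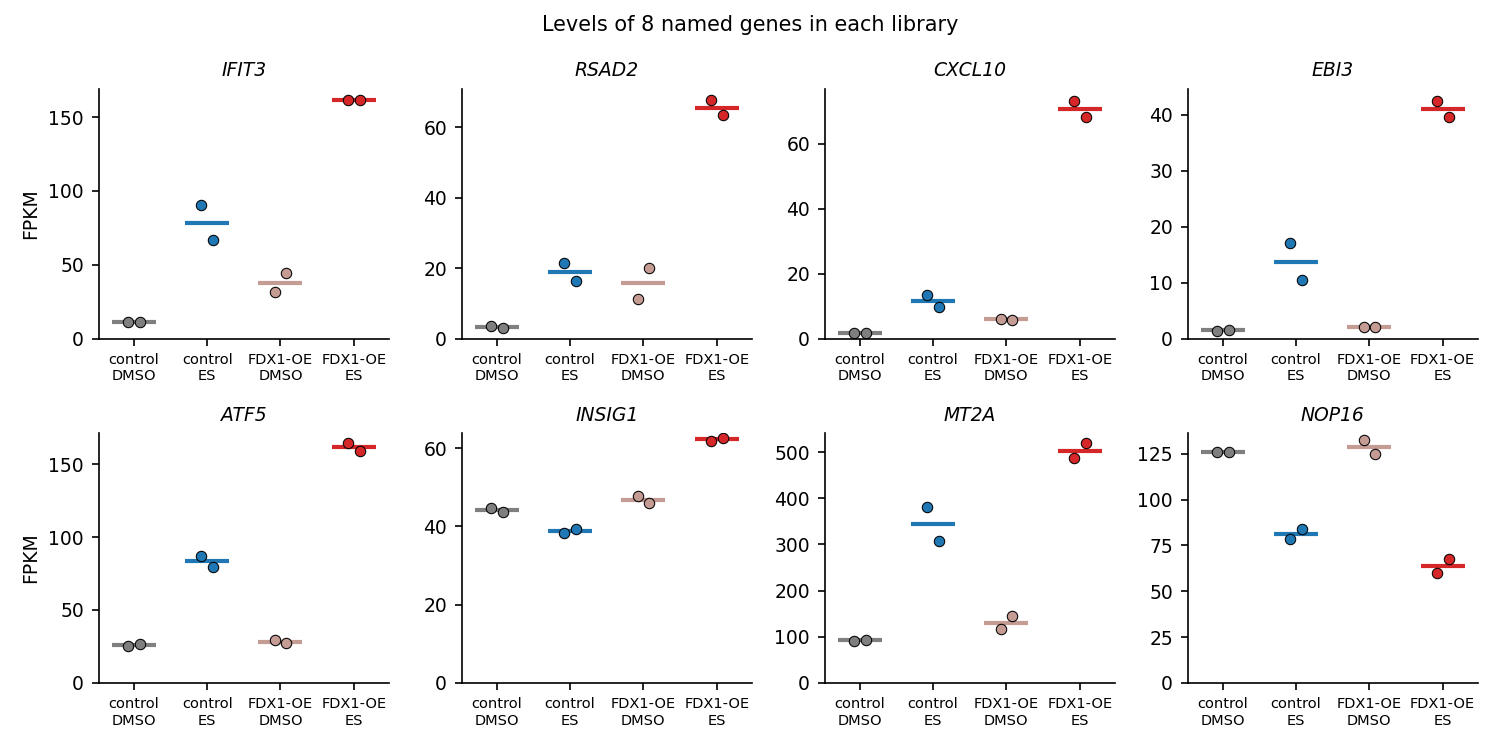
FPKM (vertical axes) of 8 named genes in each library by group (horizontal axes), where points are libraries and bars are means of 2 libraries. IFIT3 has means of 10.99, 78.5, 37.9 and 161.3 FPKM in control DMSO, control ES, FDX1-OE DMSO and FDX1-OE ES.

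The interaction asks whether the response to ES differed between FDX1-OE and control cells. The chemokine CXCL11 gained 2.82 times more (log2 difference 1.496, SE 0.17, n = 2 per group, adjusted p = 0.00268), rising from 2.42 to 23.3 FPKM in FDX1-OE cells and from 0.868 to 3.69 FPKM in control cells, but did not pass with voom (adjusted p = 0.0896). LMO2, a transcription factor of germinal-centre B cells, rose from 5.87 to 13.9 FPKM in FDX1-OE cells and was at 7.79 and 7.47 FPKM in control cells (log2 difference 1.17, SE 0.10, adjusted p = 0.00121). The stress gene CHAC1 gained 2.24 times more (log2 difference 1.16, SE 0.13, adjusted p = 0.00217), and the cholesterol gene HMGCS1 1.54 times more (log2 difference 0.63, SE 0.09, adjusted p = 0.00718).

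Of the genes tested 422 passed in the interaction, 319 with a higher and 103 with a lower value in FDX1-OE cells, and 40 of the higher genes differed by at least 2 times. With RLE scaling 244 were higher and 270 lower, and 347 main calls were shared. From ratios of mean FPKM with nothing added, 7 of the 422 had the opposite sign, among them TRIM31, whose ratio was not finite. Where the sign held, log2 differences moved both ways, from 0.925 to 0.005 for IL2RA and 0.838 to 3.65 for INPP1. The count was 176 without the filter and 222 with a pseudocount of 0.1. It was 147 and 150 without control DMSO replicates 1 and 2, 190 and 159 without FDX1-OE DMSO replicates 1 and 2, 100 without control ES replicate 2, and 79 and 164 without FDX1-OE ES replicates 1 and 2. Rises named by size had a mean of at least 5 FPKM. Besides CXCL11 and LMO2 they were TNFSF10 (2.44 times), EBI3 (2.40 times), the lymphotoxin gene LTA (2.38 times) and CXCL10 (2.30 times). The log2 difference of TNFSF10 was 1.29, but 0.745 with a pseudocount of 0.1, 0.572 with voom and 0.504 from ratios of mean FPKM. TNFSF10, EBI3 and CXCL10 did not pass with voom (adjusted p = 0.516, 0.133 and 0.11), and EBI3 did not without control DMSO replicate 2 (0.0622) or FDX1-OE ES replicate 1 (0.0707). Without the filter TNFSF10, EBI3, LTA and CXCL10 did not pass (0.092, 0.114, 0.0615 and 0.0577), nor did CXCL11 and TNFSF10 with a pseudocount of 0.1 (0.0504 and 0.183). The largest falls were those of TRIB1 (0.644 times), PRR3 (0.654 times), NR1D1 (0.667 times), GFI1B (0.668 times), TCL1A (0.679 times) and the tubulin TUBA4A (0.680 times), and of these TCL1A alone passed whichever library was left out. FDX1 passed narrowly (log2 difference 0.38, adjusted p = 0.0469), and not with RLE scaling (adjusted p = 0.069), without the filter (0.12), with a pseudocount of 0.1 (0.0596) or with any library other than control DMSO replicate 2 left out. The difference was not past the threshold for MT2A (0.06, adjusted p = 0.85), MT1X (0.40, adjusted p = 0.165), SLC30A1 (0.29, adjusted p = 0.199), SLC31A1 (0.07, adjusted p = 0.821), ATP7A (-0.02, adjusted p = 0.94), LIAS (0.09, adjusted p = 0.739), DDIT3 (0.51, adjusted p = 0.0537) and DLAT (-0.30, adjusted p = 0.0747). DDIT3 passed with the replicate block (0.0492), a mean of at least 5 FPKM (0.0445), a pseudocount of 5 (0.0389) and without control DMSO replicate 1 (0.0185), and DLAT with RLE scaling (0.0442) and with voom (0.0405).

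Camera called 13 lists in the interaction, 9 with a larger rise or smaller fall in FDX1-OE cells and 4 the other way, and 0 held with an estimated correlation (9 at an unadjusted p below 0.05). NF-kB targets were higher in 14 of 21 cases and lower in 0, or 16 and 0 adjusted over the list alone (median 0.61, adjusted p = 3.57e-13; adjusted p = 0.0751 with an estimated correlation). CCL22 (3.03 times), CCL3 (2.66 times) and CD40 (1.64 times), a receptor of B-cell activation, had the smallest p. Of 27 ATF4 stress genes 12 were higher and 0 lower, or 19 and 0 adjusted over the list alone (median 0.35, adjusted p = 7.28e-10; adjusted p = 0.0751 with an estimated correlation). ATF5 gained 1.77 times and TRIB3 1.69 times more. Of 23 cholesterol synthesis genes 5 were higher and 0 lower, or 15 and 0 adjusted over the list alone (median 0.30, adjusted p = 1.07e-08; adjusted p = 0.0751 with an estimated correlation). TM7SF2 gained 1.84 times and INSIG1 1.51 times more. The ER unfolded protein response had 3 of 21 genes higher and 0 lower, or 7 and 0 adjusted over the list alone (median 0.18, adjusted p = 0.00121; adjusted p = 0.0797 with an estimated correlation): DNAJC3 (1.39 times), EDEM1 (1.34 times) and HERPUD1 (1.29 times). Histones were higher in 3 of 11 cases and lower in 0, or 6 and 0 adjusted over the list alone (median 0.82, adjusted p = 0.00136; adjusted p = 0.0797 with an estimated correlation), a call lost with voom (adjusted p = 0.201) and without the filter (adjusted p = 0.116). Without the filter the higher genes numbered 6 among NF-kB targets, 5 among ATF4 stress genes, 2 in cholesterol synthesis, and 0 in the ER response and among histones. With voom they numbered 11 in cholesterol synthesis and 0 among histones, and with a pseudocount of 5 the histones numbered 6. The count of NF-kB targets was 8 without control DMSO replicate 2 or FDX1-OE ES replicate 1 and 9 without FDX1-OE DMSO replicate 2 or control ES replicate 2. ATF4 stress genes numbered 5 without control DMSO replicate 2, FDX1-OE DMSO replicate 2 or control ES replicate 2 and 4 without FDX1-OE ES replicate 1. Cholesterol synthesis genes numbered 8 without control ES replicate 1 and 3 without control DMSO replicate 1 or 2, FDX1-OE DMSO replicate 2, control ES replicate 2 or FDX1-OE ES replicate 2. The 3 ER genes were 0 or 1 with any library other than control ES replicate 1 left out, and the 3 histones were 0 or 1 without control DMSO replicate 2, control ES replicate 2, FDX1-OE ES replicate 1 or FDX1-OE ES replicate 2.

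Smaller counts stood behind the other lists called higher in the interaction. MHC class II genes had 2 of 13 higher and 0 lower, or 4 and 0 adjusted over the list alone (median 0.12, adjusted p = 0.00303; adjusted p = 0.116 with an estimated correlation). The pro-apoptotic BCL2 family had 3 of 12 higher and 0 lower, also adjusted over the list alone (median 0.23, adjusted p = 0.00514; adjusted p = 0.164 with an estimated correlation), a call lost without FDX1-OE ES replicate 2 (adjusted p = 0.0565). Its 3 genes, named after their values were seen, were BMF, PMAIP1 and BCL2L11. Of 21 p53 targets 3 were higher and 0 lower, or 4 and 0 adjusted over the list alone (median 0.19, adjusted p = 0.00523; adjusted p = 0.0951 with an estimated correlation), a call lost at a mean of at least 5 FPKM (adjusted p = 0.0547). The higher p53 targets numbered 1 without control DMSO replicate 2, FDX1-OE DMSO replicate 2 or control ES replicate 2 and 0 without FDX1-OE ES replicate 1. Of 21 NRF2 targets 4 were higher and 0 lower, also adjusted over the list alone (median 0.14, adjusted p = 0.00686; adjusted p = 0.27 with an estimated correlation), and 2 without control ES replicate 2. With any library other than control ES replicate 1 left out, 1 MHC class II gene passed, as with RLE scaling or a pseudocount of 0.1. Without the filter 0 MHC class II genes, 1 p53 target and 2 NRF2 targets passed.

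Ribosome biogenesis genes fell further in FDX1-OE cells in 6 of 31 cases and less in 0, or 19 and 0 adjusted over the list alone (median -0.24, adjusted p = 7.67e-13; adjusted p = 0.0751 with an estimated correlation). NOLC1 (0.732 times), NCL and LYAR (each 0.738 times) had the smallest p. Of 32 mitosis genes 3 were lower and 0 higher, or 7 and 0 adjusted over the list alone (median -0.12, adjusted p = 5.87e-07; adjusted p = 0.124 with an estimated correlation): PLK1 (0.751 times), TPX2 (0.760 times) and the cyclin CCNA2 (0.767 times). Glycolysis and hypoxia genes were lower in 2 of 28 cases and higher in 0, or 7 and 1 adjusted over the list alone (adjusted p = 0.00402; adjusted p = 0.0797 with an estimated correlation). Of 18 heat shock genes 4 were lower and 0 higher, or 7 and 1 adjusted over the list alone (median -0.18, adjusted p = 0.00523; adjusted p = 0.317 with an estimated correlation and 0.133 with fry), with HSPA8, STIP1, HSP90AB1 and FKBP4 at 0.763, 0.760, 0.781 and 0.818 times. With RLE scaling the lower genes numbered 10 in ribosome biogenesis, 6 in mitosis and 6 in glycolysis and hypoxia. Without the filter they numbered 1 in each of ribosome biogenesis, mitosis and heat shock and 0 in glycolysis and hypoxia. With voom they numbered 10, 5, 6 and 5 in these 4 lists, and a pseudocount of 0.1 left 3 in ribosome biogenesis and 2 in heat shock. With any library other than control ES replicate 1 left out, they numbered between 0 and 3 in ribosome biogenesis, 0 or 1 in mitosis and 0 or 1 in heat shock. Those of glycolysis and hypoxia were 0 or 1 with any library other than control ES replicate 1 or FDX1-OE ES replicate 2 left out.

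Interferon-stimulated genes were not called in the interaction, with 3 of 30 higher and 0 lower (median -0.01, mean 0.02, adjusted p = 0.624). This rests on the settings: the list was called down with a pseudocount of 0.1 (median -0.25, adjusted p = 0.0149), with voom (-0.253, adjusted p = 0.00385), and without FDX1-OE DMSO replicate 1 (-0.215, adjusted p = 0.000411) or control ES replicate 2 (-0.185, adjusted p = 0.0229). It was called up with a pseudocount of 5 (median 0.242, adjusted p = 0.0286) and without FDX1-OE DMSO replicate 2 (0.223, adjusted p = 0.0424). Of its 3 higher genes, IFIT5 had the opposite sign from ratios of mean FPKM. For IFIT3 the difference was -0.63 on the log2 scale (adjusted p = 0.111). Nor were OXPHOS genes, with 0 of 76 passing and 11 higher and 2 lower at an unadjusted p below 0.05 (adjusted p = 0.624). Higher and lower genes numbered 1 and 0 in each of S phase, germinal-centre B-cell genes, plasma cell genes and copper handling, 2 and 1 in iron handling, 4 and 0 among immediate early genes, and 0 and 1 in the TCA cycle. The copper handling gene was CCS, the copper chaperone for superoxide dismutase (log2 difference 0.53, adjusted p = 0.0125), named after its value was seen. The lipoylation pathway and iron-sulfur cluster assembly had 0 genes past the threshold, against 2 and 3 at an unadjusted p below 0.05. Adjusted over the list alone the counts were the same except for plasma cell genes, with 2 and 0, and immediate early genes, with 5 and 2. Immediate early genes were called up without control DMSO replicate 1 (adjusted p = 0.026). With fry, copper handling (adjusted p = 0.0469) and germinal-centre B-cell genes (0.0158) were called up. Camera pointed down for interferon-stimulated and S phase genes while their means were above 0.

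Across the 9805 genes the ES responses of control and FDX1-OE cells, which share no library, correlated with a Pearson r of 0.84 and a Spearman rho of 0.813. Genes such as IFI6, IFIT3 and MT2A were among the 2105 that rose in both, where independent lists would share 925.3, and FKBP4 and NOP16 were among the 1010 that fell in both, where independent lists would share 243.1. The genes called in opposite directions numbered 14. Of the genes called in the same direction in both, 75.1% changed more in FDX1-OE cells, with a median ratio of 1.293. The effects of FDX1-OE in DMSO and in ES correlated less, with an r of 0.342 and a rho of 0.139. They shared 40 higher genes, where independent lists would share 5.7, and 6 lower genes, where they would share 0.6, and 0 genes went opposite ways.

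**Figure D4:**
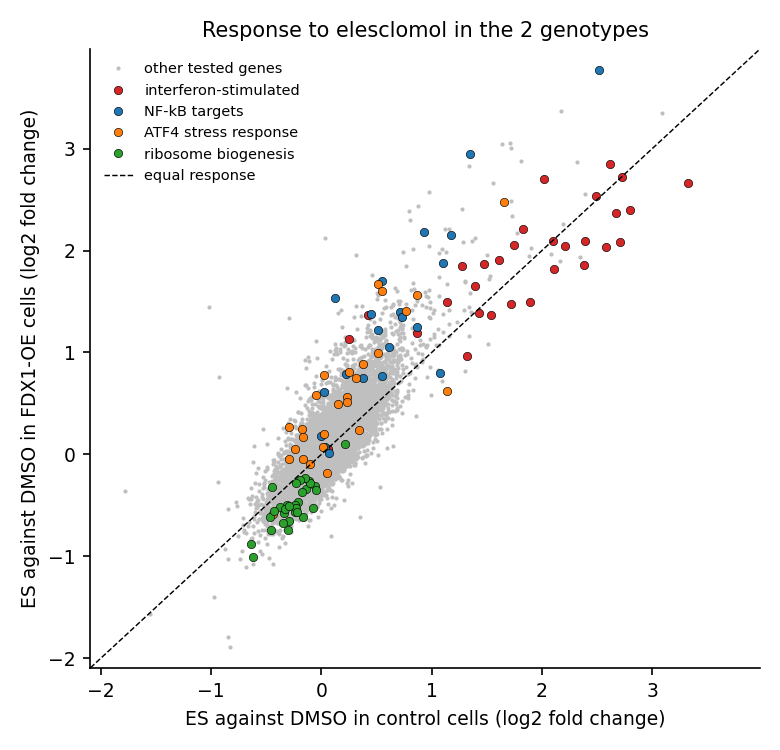
Log2 fold change of ES against DMSO in control cells (horizontal axis) and FDX1-OE cells (vertical axis), where each point is 1 of 9805 genes, the colors mark 4 gene lists and the dashed line marks an equal response. Across the genes r is 0.84, and the NF-kB targets EBI3 (2.51 and 3.78) and CCL22 (1.35 and 2.95) lie above the line.

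Lists with fewer than 5 tested members were not tested as lists. Of the metallothionein list 3 genes were tested, and MT1X and MT2A rose with ES in both genotypes, while SLC30A1 passed in FDX1-OE cells alone with no difference past the threshold in the interaction (adjusted p = 0.199). Among T and NK cell markers, CD3E rose with ES in control cells (log2 change 0.60, adjusted p = 0.00417) and FDX1-OE cells (0.35, adjusted p = 0.0346), as did LCK (0.29, adjusted p = 0.00669, and 0.47, adjusted p = 0.000168). IL7R was higher in FDX1-OE cells in ES (0.38, adjusted p = 0.00363), and PRF1 passed in 0 of the 5 comparisons. Of the 2 tested myeloid markers, named above, CD68 differed in the interaction (1.10, adjusted p = 0.00211) and FCER1G did not pass (0.40, adjusted p = 0.31). Of the epithelial and stromal markers VIM rose in control cells (0.33, adjusted p = 0.0176), DCN fell by 0.40 in control cells (adjusted p = 0.0103) and by 0.39 in FDX1-OE cells (adjusted p = 0.00651), and THY1 passed in 0 comparisons. Mitochondrially encoded genes were not analysed here.

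The 5 lists written after the values were seen hold genes around the interferon and chemokine rises. They were chosen from rises already seen, so their counts are no independent evidence, and no list test of them is given. IFNB1, which encodes interferon beta, was at 0.0836, 0.761, 1.27 and 5.90 FPKM in control DMSO, FDX1-OE DMSO, control ES and FDX1-OE ES, and IFNL3 at 0.0633, 2.27, 2.68 and 13.7 FPKM, and both were near the floor of 3 reads in control cells in DMSO. IFNB1 was higher in FDX1-OE cells in DMSO (log2 change 0.70, adjusted p = 0.00928). In the interaction its difference was 0.90 on the scale of FPKM + 1 but -0.97 from ratios of mean FPKM, so that its sign rests on the added 1. The interferon ligands IFNB1, IFNL1, IFNL2 and IFNL3, too few for a list test, each rose with ES in both genotypes. Of 11 chemokines 9 rose with ES in control cells, 11 in FDX1-OE cells, 4 were higher in FDX1-OE cells in DMSO, 9 in ES and 7 in the interaction, where CCL25 had the opposite sign from ratios of mean FPKM (1.04 and -0.171). Adjusted over the list alone the counts were 9, 11, 4, 9 and 8. Nucleic acid sensors rose in 13 of 16 cases in control cells and 14 in FDX1-OE cells, where TLR9 fell, and 5 were higher in FDX1-OE cells in DMSO. In ES 10 sensors were higher and 1 lower, and in the interaction 3 were higher, of which ZBP1 had the opposite sign from ratios of mean FPKM (0.73 and -2.20). Sensors higher and lower numbered 7 and 2 in DMSO, 11 and 1 in ES, and 3 and 1 in the interaction when adjusted over the list alone. MHC class I genes rose in 11 of 14 cases in control cells and 12 in FDX1-OE cells, and 0 passed in DMSO, 9 in ES and 4 in the interaction (1, 13 and 5 adjusted over the list alone). HLA-B rose by 1.12 in control cells and 2.21 in FDX1-OE cells on the log2 scale (interaction 1.09, adjusted p = 0.00362). Of 5 cancer-testis genes 3 rose in each genotype, 0 passed in DMSO, 3 in ES and 2 in the interaction (2, 4 and 3 adjusted over the list alone), and CSAG1 rose in FDX1-OE cells from 0.238 to 4.42 FPKM against 0.296 and 0.346 FPKM in control cells (interaction 2.09, adjusted p = 0.00182).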

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

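The pattern of low genes below was noticed in the data. Its 2 tests were written after that but before their results were seen, except for the limit on the gene families, which was set after the sums without it were seen. The results listed here stand out because the response to ES differed between FDX1-OE and control cells in a test of the difference itself, the interaction in limma or camera. They come to 422 genes, 79 without FDX1-OE ES replicate 1, and 13 lists, of which 0 held with an estimated correlation (9 at an unadjusted p below 0.05). Values below are the response in FDX1-OE cells minus that in control cells on the log2 scale, from 2 libraries per group.

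Among cytokine, chemokine and NF-kB genes the difference was 1.601 for CCL22, 1.496 for CXCL11, 1.411 for CCL3, 1.288 for TNFSF10 (0.745 with a pseudocount of 0.1; 0.572 with voom, adjusted p = 0.516), 1.263 for EBI3, 1.248 for LTA, 1.201 for CXCL10 and 0.71 for CD40. For the transcription factor LMO2 the difference was 1.166. Stress genes of the ATF4 list differed by 1.164 for CHAC1, 0.825 for ATF5 and 0.753 for TRIB3. Cholesterol synthesis genes differed by 0.876 for TM7SF2, 0.627 for HMGCS1 and 0.59 for INSIG1. In the ER unfolded protein response it was 0.474 for DNAJC3, 0.424 for EDEM1 and 0.372 for HERPUD1, and for FDX1 it was 0.384.

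Responses were lower in FDX1-OE cells for TRIB1 (-0.634), PRR3 (-0.612), NR1D1 (-0.585), GFI1B (-0.583), TCL1A (-0.558) and TUBA4A (-0.557). In ribosome biogenesis the differences were -0.45 for NOLC1, -0.439 for NCL and -0.439 for LYAR. Mitosis genes differed by -0.413 for PLK1, -0.396 for TPX2 and -0.383 for CCNA2. Of the 31 named genes called here, 16 did not pass without at least 1 library, 19 without the filter on low values and 4 with voom.

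A broader pattern went with these differences: more genes of low level were read with ES, above all in FDX1-OE cells. Genes at 0 reads went from 2653 ± 15.6 (SD, n = 2) to 1575.5 ± 24.7 in FDX1-OE cells, 1077.5 fewer, and from 2660.5 ± 84.1 to 2245.5 ± 81.3 in control cells, 415 fewer. Library depth would leave little difference once every library is thinned to the smallest total, but 1046 fewer genes remained at 0 in FDX1-OE cells and 447 in control cells. Reads from genomic DNA would fall on silent genes as on others, yet 69 olfactory receptor, taste receptor and keratin-associated genes under 0.5 FPKM gained 28.6% (95% Poisson interval 21.0 to 36.8) of the gain of 5386 other low genes per kilobase. Without that limit the families gained 766.4% of it, because of OR13A1, at a mean of 10.28 FPKM and 2859 reads in DMSO against 6419 in ES, whereas genomic DNA would add reads to all of these genes evenly.

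Depth and genomic DNA are thus each argued against as the whole cause, by the 1046 genes and the upper limit of 36.8%. A response to ES that differs between genotypes stays open, as does genomic DNA as part of the cause, since silent families gained too. RNA from other cells and differences in library preparation were not tested here.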

How the results depend on the processing

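List member counts, the limits for a move and the filter were chosen after the data were seen. The planned DESeq2 test was not run, so voom alone tested recovered reads. Of main calls of named genes and lists, 0 reversed under an alternative. In the interaction the interferon list was called both ways, and 7 of 422 genes reversed on ratios of mean FPKM. Of the results that answer a comparison, 152 stayed within their limits over the alternatives and 45 moved. For folds of named genes, 2049 kept their side of the threshold, 170 lost it and 13 gained it. For medians of lists, 632 kept it and 90 lost it, and 485 counts of list members stayed within 1.5 times while 139 did not. The level of FDX1 kept its call under every alternative, at 1.40 to 1.64 in DMSO and 1.75 to 1.97 in ES.

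Requiring a change of at least 2 times left 94 genes for ES in control cells, 293 for ES in FDX1-OE cells, 18 for FDX1-OE in DMSO, 76 for FDX1-OE in ES and 40 in the interaction, by construction. An estimated correlation left 0 lists in each of the 5 comparisons, with 4, 4, 2, 7 and 9 at an unadjusted p below 0.05, and the cause was not tested. In turn fry called 11 lists for ES in control cells, 21 for ES in FDX1-OE cells, 0 (2 unadjusted) for FDX1-OE in DMSO, 20 for FDX1-OE in ES and 14 in the interaction. By construction fry does not compare a list with other genes. Without the filter on low values 2 genes passed for FDX1-OE in DMSO and 176 in the interaction. A pseudocount of 5 left 31 genes for FDX1-OE in DMSO, and a pseudocount of 0.1 left 222 in the interaction. For these filter and pseudocount results the cause was not tested.

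Leaving out 1 library gave 15 to 64 genes and 2 to 3 lists for FDX1-OE in DMSO, 748 to 1812 genes for FDX1-OE in ES and 79 to 630 genes in the interaction. These fits hold fewer libraries. The highest of each was above the main count for FDX1-OE in DMSO and the interaction, without FDX1-OE DMSO replicate 1 and control ES replicate 1.

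The correlation of the ES responses was 0.866 over genes with a mean of at least 5 FPKM, 0.71 with voom, 0.813 as Spearman's rho and 0.778 to 0.855 without a library. That of the FDX1-OE effects was 0.309 without the filter, 0.385 at a mean of at least 5 FPKM, 0.207 with voom, 0.139 as Spearman's rho and 0.284 to 0.351 without a library. The cause was not tested.

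RLE scaling kept the gene counts, at 3805, 5456, 58, 2234 and 514, but turned the majority of called genes from higher to lower in the 2 ES responses, in FDX1-OE against control in ES and in the interaction. With the replicate number as a block the counts were 3804, 5575, 56, 2173 and 526. Deviations of libraries with the same replicate number correlated between -0.18 and 0.181, over 0.1 in 3 of 6 pairs and below 0 in the 3 pairs with control DMSO replicate 1. The numbers were therefore not taken to mark pairs. At these depths genes of few reads were below the filter, and changes among them were not tested.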

Other observations

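Both tests in this part rest on patterns noticed in the data, the test of mixed RNA was written after the values it uses were seen, and the gene pairs were chosen after their reads were seen.

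Of 30 interferon-stimulated genes 19 were higher in FDX1-OE cells in DMSO (adjusted p = 0.229 with an estimated correlation and 0.099 with fry), 0 without the filter and 6 without control DMSO replicate 2. IFIT3 was at 37.9 FPKM against 10.99 FPKM in control cells. With ES 28 of the 30 rose in control cells and 29 in FDX1-OE cells. RNA of ES-treated FDX1-OE cells in the FDX1-OE DMSO libraries would raise all genes that ES raises by the same share. The share needed was 11.74% (median of 28 interferon genes, quartiles 10.11 to 17.06) but 1.74% for 5 genes of the ATF4 list (quartiles 0.99 to 3.2), a gap of 10.0 percentage points. The share needed by 13 NF-kB targets was 1.28% (quartiles -4.55 to 3.75). A mixture is therefore argued against as the whole cause, and a low interferon response in FDX1-OE cells without the drug may be part of the genotype's effect or of how the cells were made, which was not tested.

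Some of the largest falls with ES were of genes with a near-identical copy, to which reads might have moved. In that case the summed reads of a gene and its copy would hold. They still fell by more than 0.5 on the log2 scale in 3 of 4 pairs. RASA4 with RASA4B changed by -1.17 and GPR89A with GPR89B by -0.56 in control cells, and SLX1B with SLX1A by -1.38 in FDX1-OE cells. GATD3B with GATD3A changed by -0.27 in FDX1-OE cells, so that moved reads stay open for this pair. Reads shared between the copies could not be told apart from the values. RASA4 went from 1770 to 158 reads with ES in control cells, while RASA4B went from 795 to 939. Leaving out reads that match both copies would lower the sum as well. The test cannot tell such a loss from a fall of the gene.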
